A study of Mus musculus with 7 samples.

How the data were processed

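Total RNA of mouse whole neocortex (strain C57BL/6, extracted with Trizol) was labelled with biotin and hybridised to 7 one-colour Affymetrix arrays, 1 per sample. Per the labels, 4 samples were CKO, with a genotype naming COUP-TFI and Nex-Cre, and 3 were wild type (WT). All 7 had an RNA integrity number of 10 and an input of 0.2 µg. The age of the tissue is not given in the sources used here. The labels do not say that each array came from a separate animal, so p-values measure the spread between these samples, which may be technical in part. Arrays are named by their group and the number in their labels (CKO 1, CKO 4, CKO 34, CKO 43, WT 6, WT 27 and WT 38). These numbers were shared by no samples of different groups and pair nothing.

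The authors deposited log2 signals made with RMA in Affymetrix Expression Console, per the submitters' processing notes; the version and the genome build are not given in the sources used here, and no coordinates are printed for that reason. The 7 deposited columns shared nearly 1 distribution: values of equal rank differed between arrays by a median of 0.000811 and at most 0.0256. The median log2 signal was 8.23 on each array. Array lot was inferred from the array identifiers in the labels, and whether it reflects a batch of processing is not given in the sources used here. Lot 1 held 2 CKO arrays, CKO 1 and CKO 4. Lot 2 held 2 CKO and 2 WT arrays, CKO 34, CKO 43, WT 27 and WT 38. Lot 3 held 1 array, WT 6.

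Of 35468 probe sets, 21786 had 1 gene symbol in the platform annotation, 1621 had several and 12061 had none. Of those with 1 symbol, 21695 were matched by Entrez identifier to the mouse RefSeq gene table of assembly GRCm38.p6, used for names alone, and 0 symbols needed updating. Probe sets with a mean over all arrays below the 25th percentile (a log2 signal of 6.84) were left out. The brightest probe set stood for each of the 998 symbols that had several, which left 16144 genes. Probe sets with several symbols or none were named nowhere. The number of arrays limits the precision.

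CKO was compared with WT over all 7 arrays with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with 5 residual and 3.28 prior degrees of freedom, no covariate, and Benjamini-Hochberg adjustment at 0.05. Errors beside log2 differences are limma's standard errors (SE), and adjusted p-values of genes come from limma. Gene lists were fixed before the data were examined. Of 33 lists, 30 had at least 5 genes tested. These were compared with the other genes by camera with a preset inter-gene correlation of 0.01, and beside it by camera with an estimated correlation and by fry. Camera with an estimated correlation also refers its statistic to the 5 residual degrees of freedom, which makes it stricter by itself. Counts of members past 0.05 were made over all genes and adjusted over the list alone. The target gene and the gene at the driver locus were also given an exact permutation test over all 35 splits of the 7 arrays. Figures were drawn with matplotlib 3.10.9.

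The genes named were fixed by rule before the data were examined. The rule took Nr2f1 and Neurod6. It took the 12 largest rises and 12 largest falls among genes past the threshold with no overlap between groups or, with fewer than 5 in a direction, the 5 smallest p-values in that direction. It also took up to 4 members of each list past the threshold over all genes or, with none, the 2 with the smallest p. Predicted genes without a descriptive symbol were not named among the largest changes. Fewer than 5 genes passed in each direction, so the fallback applied. Some genes taken from the lists went through every alternative but are not described one by one. Members past the threshold over their list alone but outside this rule, and the genes that open the closing observations, were chosen after their values were seen.

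The fit and the list tests were tested on simulated data of 16144 genes with the spread of these arrays. With 67, 67 and 66 genes changed by a log2 value of 0.3, 0.6 and 1, the shares recovered were 52.2%, 86.6% and 97.0%. Of 164 genes called, 7 were unchanged ones. On the real arrays 4 genes were called, so the adjustment was more lenient in the simulation. The shares recovered there may therefore overstate the recovery in these data. All 20 lists shifted by 0.15 were called, as were 0 of 100 unshifted lists. The simulated genes varied independently of each other, so these list counts leave out correlation between genes.

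Alternatives fixed before the data were examined were another normalization, the filter on dim probe sets, averaging of probe sets, the variance model, array weights, array lot as a fixed block, as a random block and within lot 2, Y-linked signal as a covariate, all probe sets, a threshold of 0.1, the other list tests and leaving out each array. A covariate of striatal signal, the mean of Isl1, Six3, Ebf1, Drd2 and Penk, was added after the data were seen. It was chosen after the values of all members of the striatal list, and how they varied together, had been viewed, together with 9 other genes. Sets of 3 genes first picked for that test because they showed the behaviour were dropped in favour of all other members of the list.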

Results

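Gene expression was measured in mouse whole neocortex in 4 CKO and 3 WT samples, on 1 array each. CKO names samples whose genotype combines COUP-TFI with Nex-Cre. COUP-TFI, encoded by Nr2f1, is an orphan nuclear receptor that patterns the areas of the neocortex, and Nex-Cre drives recombination in postmitotic glutamatergic neurons from the Neurod6 locus. The comparison asks which transcripts differ in the neocortex between the 2 genotypes. Values are RMA log2 signals, differences are CKO minus WT, and 16144 genes were tested with limma.

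Nr2f1 (probe set 10410766) had a mean log2 signal of 10.68 ± 0.084 (SD, n = 4) in CKO and 11.04 ± 0.143 (SD, n = 3) in WT. The difference was -0.36 (SE 0.074), or 0.779 of the WT signal, and each CKO array lay below each WT array. Neurod6 (probe set 10544936) had 12.66 ± 0.056 (SD, n = 4) in CKO and 12.86 ± 0.103 (SD, n = 3) in WT, a difference of -0.20 (SE 0.057), again without overlap between the groups. Each gene gave a two-sided exact permutation p of 0.0286, the smallest that 35 splits allow. Neither passed limma's adjustment over all genes, with an adjusted p of 0.435 for Nr2f1 and 0.711 for Neurod6. Both passed when adjusted over the list alone. Whether the Nr2f1 probe set lies inside the deleted part is not known here, so a partial loss of signal neither checks nor contradicts the labels. Within lot 2 the differences were -0.37 for Nr2f1 and -0.23 for Neurod6. With a covariate of striatal signal, chosen after the data were seen, they moved to -0.19 and -0.09.

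Syt6 and Rasgrf1 rose and Tenm1 and Kcnab1 fell in CKO. Syt6 (probe set 10494945), a synaptotagmin and a marker of layer 6 corticothalamic neurons, rose 1.60-fold, by 0.67 (SE 0.041) on the log2 scale, with an adjusted p of 0.00220. Rasgrf1 (probe set 10587699), a guanine nucleotide exchange factor that activates Ras, rose 1.45-fold, by 0.54 (SE 0.052). Tenm1 (probe set 10604292), a teneurin adhesion protein, fell to 0.576 of the WT signal, a difference of -0.79 (SE 0.080). Kcnab1 (probe set 10492402), an accessory subunit of voltage-gated potassium channels, fell to 0.668 of WT, a difference of -0.58 (SE 0.060). The adjusted p of these 3 genes was 0.0345. For each of the 4 genes all 4 CKO arrays lay on one side of all 3 WT arrays.

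**Figure D1:**
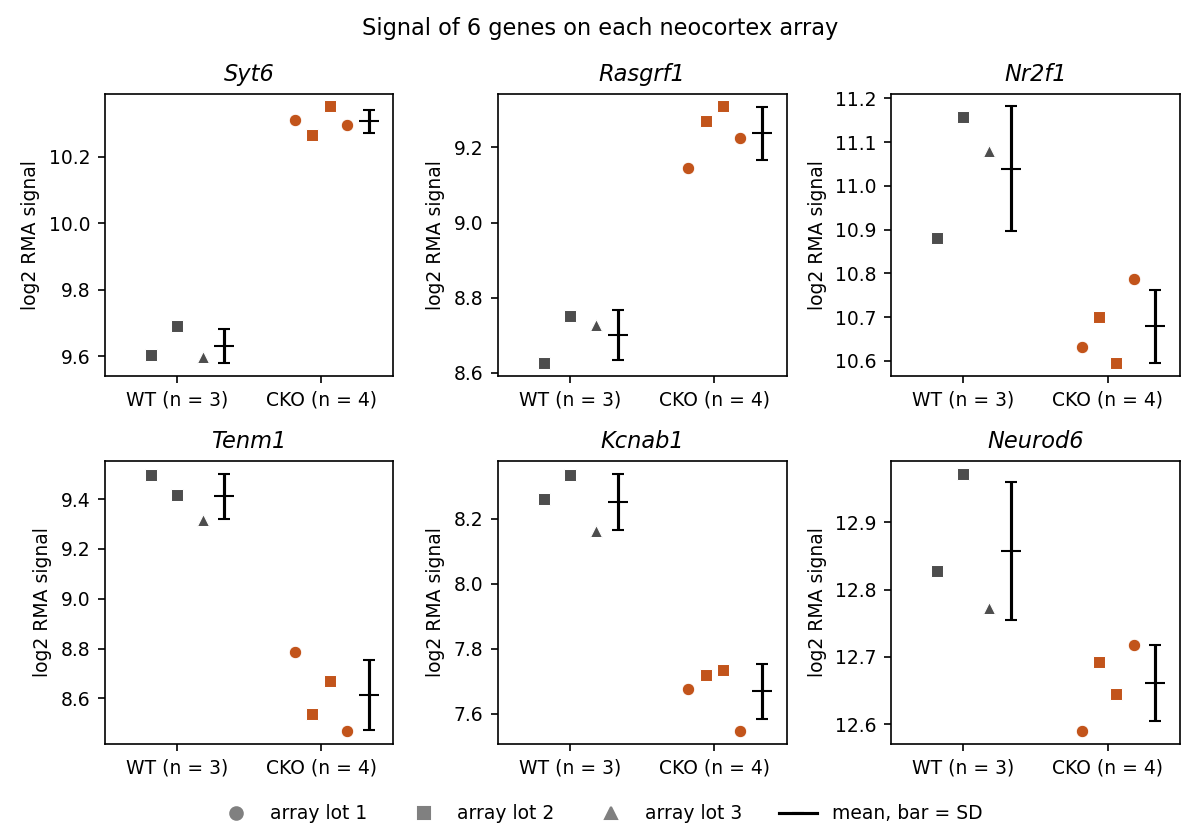
Log2 RMA signal of 6 genes on each array, with WT in grey, CKO in orange and the marker shape giving the array lot; the bars are the mean and SD. Syt6 and Rasgrf1 lie higher in CKO, with mean log2 signals of 10.31 and 9.24 against 9.63 and 8.70 in WT, and Tenm1, Kcnab1, Nr2f1 and Neurod6 lie lower, without overlap between the groups.

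These 4 genes, 2 higher and 2 lower, were all that passed an adjusted p of 0.05 among 16144, and also all that passed 0.1. At an unadjusted p under 0.05 there were 1096 genes, 674 higher and 422 lower in CKO, where 807.2 would be reached by chance. The groups did not overlap for 1353 genes, 870 higher and 483 lower, or 8.38% of genes, where chance gives 5.71%. Neither count stood out from other splits of the 7 arrays, of which 6 gave at least as many genes at that p and 6 at least as many without overlap. No genes passed with array lot as a fixed block (611 at an unadjusted p under 0.05) or within lot 2 alone (486), with limma in each case. These 2 settings give each gene the same difference, as lots 1 and 3 held 1 group each, so they are not separate checks. With lot as a random block 4 passed. Within lot 2 the differences were 0.66 for Syt6, 0.60 for Rasgrf1, -0.85 for Tenm1 and -0.57 for Kcnab1. Syt6 was the 1 gene that passed when any array other than CKO 1 was left out; without CKO 1, 6 genes passed, of which 3 were among the 4.

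Genes next in order by p did not pass the adjustment over all genes. Among those higher in CKO, Slit1, a secreted axon guidance ligand, differed by 0.26 (SE 0.039, adjusted p 0.161). Ppp1r1b, which encodes the dopamine-regulated phosphatase inhibitor DARPP-32, differed by 0.43 (SE 0.068, adjusted p 0.251). Fgf18, a fibroblast growth factor, differed by 0.37 (SE 0.063, adjusted p 0.301). Among those lower in CKO, Npy, the neuropeptide Y gene of a class of interneurons, differed by -0.51 (SE 0.064) and Htr2a, a serotonin receptor, by -0.56 (SE 0.070), each with an adjusted p of 0.10. Flrt3, a membrane protein of cell adhesion and axon guidance, differed by -0.42 (SE 0.057, adjusted p 0.134).

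Markers of deep-layer neurons differed in both directions. Of 14 layer 6 markers tested, 1 passed over all genes, Syt6, and 6 passed when adjusted over the list alone, 4 higher and 2 lower in CKO. The higher ones were Syt6, Ppp1r1b, Hs3st4 (0.20, SE 0.065) and Fezf1 (0.23, SE 0.077). The lower ones were Ntsr1, a neurotensin receptor of corticothalamic neurons, with -0.47 (SE 0.114), and Sox5, a transcription factor of early-born corticofugal neurons, with -0.14 (SE 0.049). The list as a whole did not shift against other genes (median 0.05, camera adjusted p 0.317). Of 20 layer 5 markers, 4 passed adjusted over the list alone. Bcl11b, the transcription factor CTIP2 of subcerebral neurons, was higher by 0.15 (SE 0.040), as was Igfbp4 by 0.15 (SE 0.041). The neurofilament genes Nefm (-0.77, SE 0.130) and Nefl (-0.98, SE 0.274) were lower. No layer 5 marker passed over all genes with limma (5 had an unadjusted p under 0.05), and the list did not shift (camera adjusted p 0.878). Of 10 subplate markers 1 passed, Kcnab1, and that list did not shift either (camera adjusted p 0.404).

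Callosal and upper-layer markers moved little as groups. Of 14 callosal markers, 3 passed adjusted over the list alone and 0 over all genes with limma (4 had an unadjusted p under 0.05). Lpl, the lipoprotein lipase gene, was lower by -0.55 (SE 0.076), and Gfra2, a receptor of the GDNF family, was higher by 0.38 (SE 0.0999), as was Chn2 by 0.15 (SE 0.044). The callosal list had a camera adjusted p of 0.878. None of 13 upper-layer markers passed on either count with limma (2 had an unadjusted p under 0.05). Inhba (-0.30, SE 0.108) and Pou3f4 (0.32, SE 0.135) had the smallest p-values, and the list had a median of -0.03 and a camera adjusted p of 0.203. Pou3f4 was at 10.42 on WT 27 against 10.88 on WT 6 and 10.85 on WT 38. Its lowest CKO array was CKO 4, at 10.77. The striatal markers Isl1 and Six3 were likewise lowest on WT 27 and, among CKO arrays, on CKO 4. Whether the difference of Pou3f4 belongs to upper-layer neurons was not tested.

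Area markers were mixed. Of 10 sensory and caudal markers, 4 passed adjusted over the list alone and 0 over all genes with limma (5 had an unadjusted p under 0.05). Tenm3, a teneurin, was lower by -0.48 (SE 0.084), the Wnt ligand gene Wnt7b by -0.22 (SE 0.070) and the cadherin gene Cdh6 by -0.20 (SE 0.063), while the retinoic acid binding protein gene Crabp1 was higher by 0.40 (SE 0.125). The list had a camera adjusted p of 0.185. Of 8 rostral markers, 6 had a negative difference and the list lay lower, with a median of -0.11 (camera adjusted p 0.0288). This call was lost with an estimated correlation (adjusted p = 0.583). The 1 member that passed adjusted over the list alone went the other way: Etv5, an ETS transcription factor, was higher by 0.32 (SE 0.062), and its second probe set gave 0.36. Lmo3 differed by -0.14 (SE 0.045). The list's call was also lost without CKO 4, WT 27 or WT 38, with array weights, with a filter at the 50th percentile and with the striatal covariate.

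**Figure D2:**
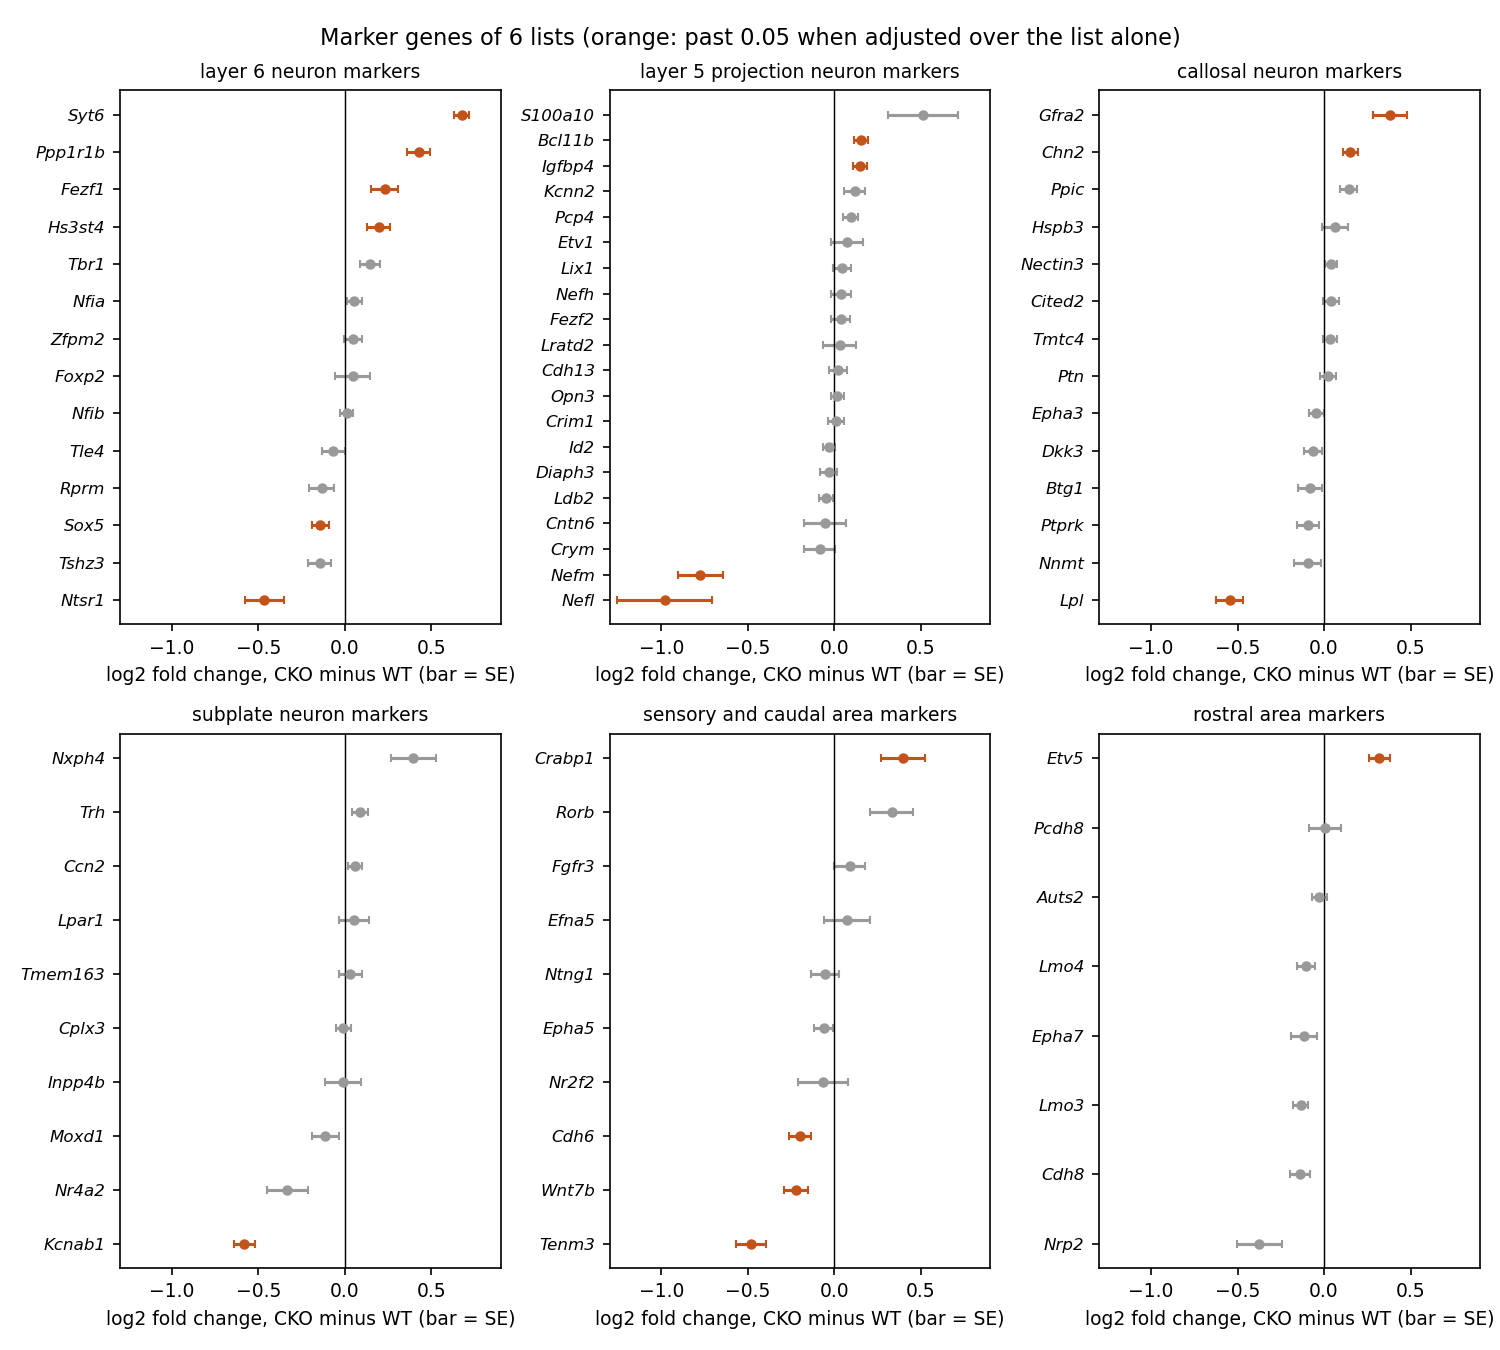
Log2 difference (CKO minus WT, points) with its SE (bars) for each gene of 6 marker lists; orange marks genes past 0.05 when adjusted over the list alone. Members of one list lie on both sides of 0, with Syt6 at 0.67 and Ntsr1 at -0.47 among layer 6 markers and Bcl11b at 0.15 and Nefl at -0.98 among layer 5 markers.

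Genes of dividing cells and progenitors lay slightly higher in CKO by camera with the preset correlation, with groups that overlapped for 3 of the 4 lists when averaged per array. Of 23 cell division genes 22 had a positive difference, with a median of 0.11 (camera adjusted p 1.1e-05; adjusted p = 0.692 with an estimated correlation). The mitotic kinase gene Plk1 (0.19, SE 0.047) and the topoisomerase gene Top2a (0.13, SE 0.042) had the smallest p-values. Of 14 radial glia markers 13 were positive, with a median of 0.11 (camera adjusted p 0.00442; adjusted p = 0.504 with an estimated correlation). Of these Sox2, a transcription factor of neural progenitors, was higher by 0.20 (SE 0.048) and passed adjusted over the list alone; Emx2 differed by 0.29 (SE 0.093). All 10 intermediate progenitor markers were positive, with a median of 0.08 (camera adjusted p 0.0211; adjusted p = 0.692 with an estimated correlation), led by Neurod1 (0.18, SE 0.061) and Btg2 (0.13, SE 0.061). Of 12 astrocyte markers 11 were positive, with a median of 0.09 (camera adjusted p 0.0336; adjusted p = 0.692 with an estimated correlation), led by Sox9 (0.16, SE 0.063) and Acsbg1 (0.11, SE 0.049). No member of these 4 lists passed over all genes with limma; 7, 4, 1 and 2 members had an unadjusted p under 0.05. WT 38 was the lowest of the 7 arrays for all 4 lists, at -0.16 for cell division genes, -0.10 for radial glia, -0.14 for intermediate progenitor and -0.09 for astrocyte markers relative to the mean of the 7. WT 6 (0.029) lay above CKO 1 (0.028) and CKO 34 (0.015) for cell division genes, WT 27 (0.05) above CKO 1 (0.01), CKO 34 (-0.05) and CKO 43 (0.05) for intermediate progenitor markers, and WT 6 (0.01) above CKO 34 (-0.02) for astrocyte markers. Without WT 38 the median of the cell division list went from 0.11 to 0.06, radial glia from 0.11 to 0.08, intermediate progenitor from 0.08 to 0.05 and astrocyte from 0.09 to 0.05; the means went from 0.10 to 0.05, 0.11 to 0.09, 0.09 to 0.04 and 0.09 to 0.07. Red blood cell genes (3 tested) were also lowest on WT 38, at -0.62, and highest on CKO 4, at 0.37. Of these Hbb-y, an embryonic globin gene, was at 8.30 on WT 38 and between 9.77 and 10.97 on the other 6 arrays, a difference between the groups of 0.75 (SE 0.449, adjusted p 0.742). The intermediate progenitor list lost its call without CKO 4, CKO 43, WT 6 or WT 38, with array weights, with the Y-linked covariate and with lot as a fixed block, and the astrocyte list without CKO 1, WT 27 or WT 38, with array weights and with the striatal covariate.

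Striatal markers were higher in CKO. Of 13 tested, 12 had a positive difference, 6 passed adjusted over the list alone and 0 over all genes with limma (7 had an unadjusted p under 0.05), and the median was 0.21 (camera adjusted p 1.1e-05; adjusted p = 0.504 with an estimated correlation). The LIM homeobox gene Isl1 differed by 0.83 (SE 0.281), Ebf1 by 0.79 (SE 0.207), Six3 by 0.50 (SE 0.170) and the dopamine receptor gene Drd1 by 0.19 (SE 0.066). Zfp503 (0.24, SE 0.063) and Ppp1r1b, which is also a layer 6 marker here, passed too. Six3 was at 7.48 on WT 27 against 7.98 on WT 6 and 8.06 on WT 38. On CKO 4 the list averaged -0.03 relative to the mean of the 7 arrays, against 0.10 to 0.27 on the other CKO arrays and -0.25 to -0.10 on the WT arrays. Of 13 meningeal and choroid plexus markers 12 were positive, with a median of 0.15 (camera adjusted p 0.0138; adjusted p = 0.583 with an estimated correlation), led by Slc6a13 (0.22, SE 0.064) and the collagen gene Col1a2 (0.33, SE 0.104). The meningeal call was lost without WT 6, without WT 27 or with the striatal covariate.

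Synaptic genes lay lower by a small amount. Of 30 genes for glutamate receptors and the excitatory synapse, 19 had a negative difference, with a median of -0.03 (camera adjusted p 0.0138; adjusted p = 0.692 with an estimated correlation). None passed on either count with limma (6 had an unadjusted p under 0.05). The metabotropic receptor gene Grm7 differed by -0.28 (SE 0.071) and the kinase gene Camk2b by -0.29 (SE 0.092). Without WT 38 the median turned to 0.03 and the call was lost, as it was without CKO 4, with array weights and with a filter at the 50th percentile.

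**Figure D3:**
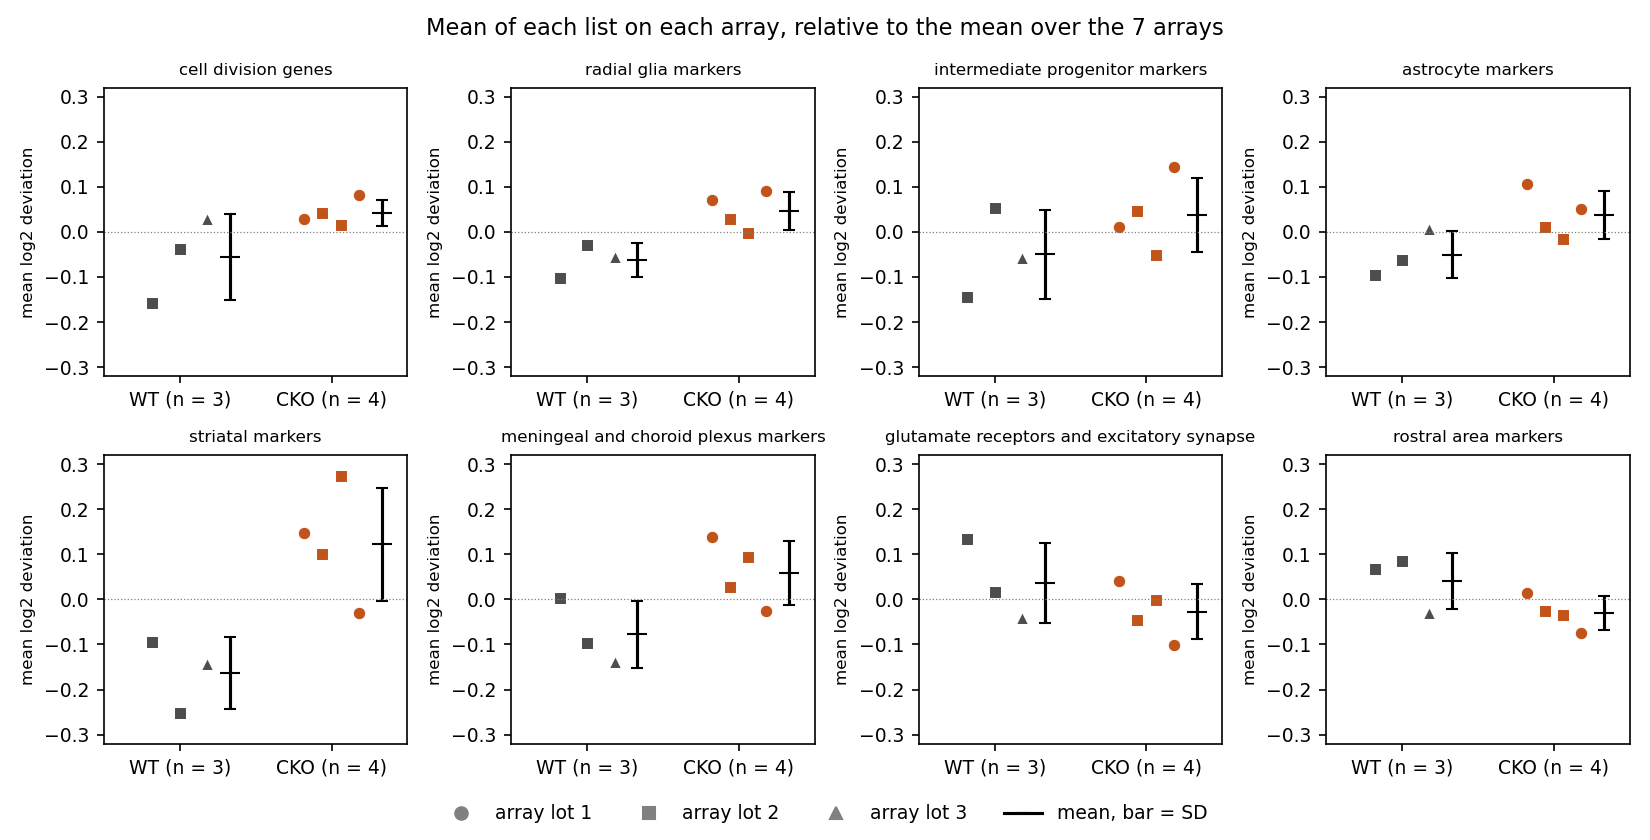
Mean of 8 gene lists on each array, as log2 deviation from each gene's mean over the 7 arrays, with WT in grey, CKO in orange, marker shape giving the array lot, and bars the mean and SD. The lists differ in the spread within a group: cell division genes lie at -0.16 on WT 38 and 0.03 on WT 6, and striatal markers lie at 0.27 on CKO 34 and -0.03 on CKO 4.

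The other lists did not shift over all arrays. Of 57 axon guidance genes, 2 passed adjusted over the list alone, Slit1 and the netrin receptor gene Neo1 (-0.20, SE 0.043), and the list had a camera adjusted p of 0.121. Of 42 potassium channel genes Kcnab1 alone passed on either count (camera adjusted p 0.761). Of 20 interneuron markers Npy passed adjusted over the list alone, while the serotonin receptor gene Htr3a differed by -0.60 (SE 0.166); the list had a camera adjusted p of 0.477. Of 12 thalamic markers Plekhg1 (0.22, SE 0.056) passed adjusted over the list alone (camera adjusted p 0.459). The camera adjusted p was 0.357 for radial migration genes, 0.404 for cadherins, 0.459 for activity-induced genes, 0.730 for nuclear receptors and 0.404 for Cajal-Retzius markers. It was 0.187 for oligodendrocyte lineage, 0.404 for microglia, 0.301 for endothelial and mural cell and 0.357 for hippocampal markers. It was 0.730 for stress genes, 0.338 for apoptosis and p53 target genes and 0.0531 for ribosomal protein genes. With limma, 0 of 203 members of these 12 lists passed on either count, and 15 had an unadjusted p under 0.05. The microglial gene Aif1 differed by -0.36 (SE 0.110) and the nuclear receptor gene Esrrg by 0.61 (SE 0.172). Red blood cell genes (3 tested) and Y-linked genes with Xist (4 tested) were too few for camera, as was the target list of 2.

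In all, 8 of 30 lists were past the threshold with the preset correlation, 6 higher and 2 lower. None passed with an estimated correlation, where the smallest adjusted p was 0.504 and 2 lists had an unadjusted p under 0.05. None passed with fry, where the smallest adjusted p was 0.124 and 5 had an unadjusted p under 0.05; fry's test for change in either direction called 12. The median, mean and test of 6 lists differed in sign: layer 5, subplate, callosal, radial migration, cadherin and potassium channel genes. Within lot 2, 7 of the 8 lists were past the threshold, as with lot as a fixed block. Within lot 2 the cell division (adjusted p 2.65e-10), striatal (1.1e-07) and radial glia (0.0036) lists were past the threshold in the same direction as over all arrays, with camera and the preset correlation, and the intermediate progenitor list was not (0.0671). WT 38, the lowest array for the cell division and radial glia lists, is 1 of the 2 WT arrays of lot 2. It weighs more there than over all arrays, so these 2 calls are no check on it. For the striatal list, lot 2 held the highest array, CKO 34 (0.27), and the lowest, WT 27 (-0.25). The lowest CKO array, CKO 4 (-0.03), lay outside lot 2. The striatal call within lot 2 is therefore no independent check either. Within lot 2 but not over all arrays, 4 more lists passed: axon guidance (median -0.07, adjusted p 0.000532) and Cajal-Retzius genes (median -0.11, 0.0106), which also passed with lot as a fixed block, and interneuron and microglia markers (0.0499 each), which did not.

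The arrays did not part by genotype along a single leading component. The first component held 27.7% of the variance and set WT 38 apart, at 15.2 against -7.0 to 1.8 for the other 6 arrays. The second held 23.3%; WT 6 (12.1) and WT 27 (5.8) lay above the CKO arrays, which lay between -6.8 and -1.7, and WT 38 lay among these at -1.9. Pearson correlations across genes, which are not independent replicates, ran from 0.993 to 0.997 over the 21 pairs of arrays, and the highest was between CKO 1 and CKO 4. Xist, the RNA that silences one X chromosome in females, was at 13.08 on CKO 43 and between 6.22 and 6.39 on the other 6 arrays. Uty, a Y-linked gene, was at 5.44 on CKO 43 and between 9.68 and 9.87 on the others.

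**Figure D4:**
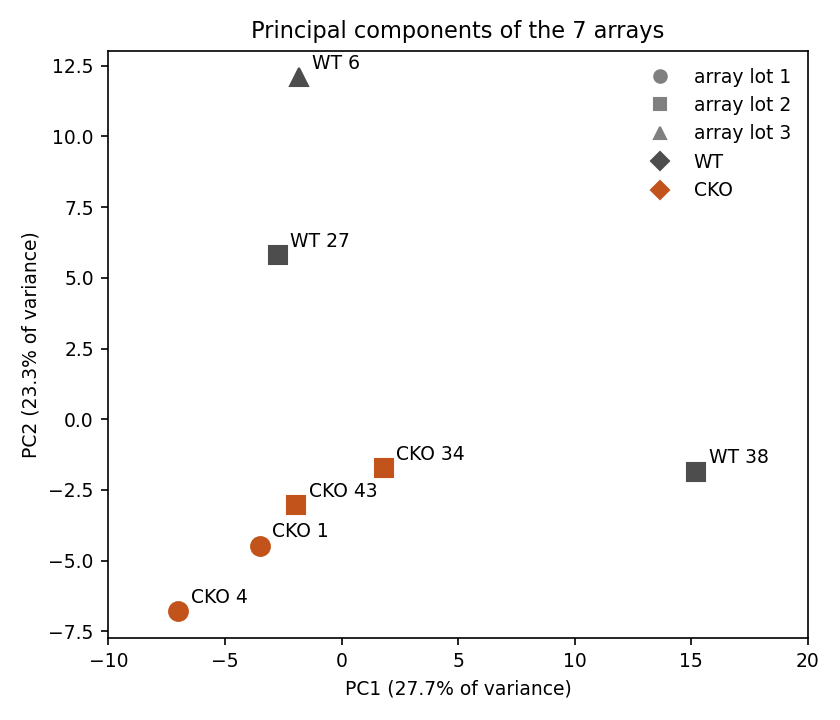
First and second principal component of the 7 arrays over 16144 genes, in units of log2 signal, with WT in grey, CKO in orange and marker shape giving the array lot. WT 38 lies at 15.2 on the first component, and WT 6 and WT 27 lie at 12.1 and 5.8 on the second, above the 4 CKO arrays.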

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

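The tests of array lot, of the female array, of WT 38, of correlation between genes, of striatal tissue, and of other splits for the gene counts and for the list members were chosen after the results were seen; the test of other splits for the list count was planned before its result. Of 99 results tested for 1 CKO array far from the other 3, 11 stood out by Dixon's ratio at its 95% critical value for 4 samples, where chance gives about 5%. Of the 11, 4 are sex-linked genes on the same array and count as 1 observation. For the 1096 genes at an unadjusted p under 0.05, 7 of the 35 splits, the real one included, gave as many and the highest other gave 1450; for the 1353 genes without overlap these were 7 of 35 and 2417, so chance cannot be excluded for either count. The split of lot 2 from the other 3 arrays was among those with as many on both counts (1097 and 1633), and 611 genes at that p were left with lot as a fixed block. Over all lists, 10 of the 35 splits gave at least the 8 lists of the real split and the highest other gave 13, so chance cannot be excluded for the list count; the split of lot 2 from the other arrays gave 9, and 11 lists passed within lot 2. By contrast 29 distinct members of the 30 lists passed adjusted over their list alone in the real split, and the highest other split gave 16 (1 of 35 splits reached 29). The real split stood out on that count, at the smallest share that 35 splits allow. This test was chosen after the results were seen, beside those of other counts, so chance is not excluded by it.

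On CKO 43, Xist (ratio 0.987) was at 13.08 against 6.31 to 6.39 on the other CKO arrays, and Eif2s3y (0.989), Kdm5d (0.98) and Uty (0.957) were at 5.16, 7.02 and 5.44 against at least 10.62, 10.03 and 9.68. Slc4a1, a red blood cell gene, was lower on CKO 43 (8.45 against 8.68 to 8.69, ratio 0.95). On CKO 1, AA388235 was at 6.07 against 8.68 to 8.92 on the other CKO arrays (ratio 0.915) and Cdh5, an endothelial cadherin gene, at 10.17 against 9.93 to 9.97 (ratio 0.839). On CKO 4, Isl1 was at 7.74 against 8.70 to 8.86 (ratio 0.86), Tenm3 at 10.91 against 11.12 to 11.16 (0.869), Rps25 at 11.88 against 11.99 to 12.01 (0.88) and Rnd2 at 12.48 against 12.23 to 12.26 (0.872).

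The first pattern weighed is the 4 genes past the threshold. Of the 35 splits of the 7 arrays into 4 and 3, 1, the real one, gave at least 4 genes and the highest other gave 2. The split of lot 2 from the other arrays was among those with 2. The real split stood out on this count, at the smallest share that 35 splits allow. As the test was chosen after the result was seen, chance is not excluded by it. Array lot, which was inferred from the array identifiers, is argued against as the whole cause by lot 2, where the largest unadjusted limma p of the 4 was 0.000467 and 98.0% to 112.1% of each log2 difference was kept; these arrays also helped to pick the genes, and with 2 arrays a side none passed the adjustment. The 1 array with female signal is argued against as the whole cause by the fit without it (largest unadjusted limma p 3.58e-05, 96.7% to 102.8% kept). The arrays left also helped to pick the genes, so a small unadjusted p there was likely beforehand. Of the 4 genes, 3 then missed the adjusted threshold, with an adjusted limma p for Kcnab1 of 0.116 (0.0323 to 0.607 over its alternatives). A response to the genotype stays open as a hypothesis, found and tested on the same arrays. The labels name no group with Nex-Cre alone. Loss of Nr2f1 and the driver at the Neurod6 locus therefore cannot be told apart. Litter, age and dissection were not tested.

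The second pattern is the higher radial glia and cell division lists, which were lowest on WT 38, as were red blood cell genes (-0.62); the blood content and age of that sample were not tested as causes. For cell division genes, the difference of the mean per array went from 0.10 (95% interval -0.03 to 0.22) to 0.0462 without WT 38 (-0.04 to 0.13), so that array may account for their shift. For radial glia markers it went from 0.11 (0.03 to 0.19) to 0.0887, with an interval from -0.00065 to 0.18 at 4 residual degrees of freedom, so the test leaves WT 38 open as a cause. As WT 38 was the lowest array for both lists, leaving it out had to shrink both differences. The interval for cell division genes included 0 before, so the test cannot show that their shift came from WT 38. Both lists stayed past the threshold without it (larger camera adjusted p 0.0363), but with a preset correlation that sets members as nearly independent. Neither list passed with an estimated correlation (smaller camera adjusted p 0.504), so members that vary together between arrays may account for the calls in part. That test also uses the 5 residual degrees of freedom, which weakens a call by itself. The lost calls therefore do not single out correlation. The lists differed in how far their members varied together. The estimated correlation was 0.41 for cell division genes (unadjusted camera p 0.143) and 0.05 for radial glia markers (unadjusted camera p 0.0336). For radial glia markers the lost call thus rests in part on the adjustment over 30 lists.

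The third pattern is the higher striatal list. Differing amounts of striatal tissue or cells may be a cause: Isl1, Six3, Ebf1, Drd2 and Penk varied between arrays of one group, and Foxp1, Meis2 and other members are also expressed in neocortex. With the mean of those 5 genes as a covariate, the difference of the mean of all 8 other members tested went from 0.14 (SE 0.028) to 0.115 (SE 0.045), 82.6% of its size. It lies 2.58 SE from 0, but with 4 residual degrees of freedom its 95% interval runs from -0.01 to 0.24, so the test leaves this open. The members moved in opposite directions. Ppp1r1b, also a layer 6 marker here, went from 0.43 to 0.50, Drd1 from 0.19 to 0.31, Gpr6 from 0.14 to 0.27 and Rgs9 from 0.03 to 0.04. Foxp1 went from -0.06 to -0.19, Rarb from 0.10 to -0.14, Meis2 from 0.05 to -0.01 and Zfp503 from 0.24 to 0.15. The share kept by the mean therefore does not describe the members. The covariate was picked after the values of the list were viewed and itself differs between the groups, and for both reasons tissue and genotype cannot be told apart for these genes.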

How the results depend on the processing

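The striatal covariate was added after the data were seen; the other alternatives were planned. The count of 4 genes became 1 with array weights, with the Y-linked covariate and with all probe sets tested, and 0 with lot as a fixed block, within lot 2 (fewer arrays) and with the striatal covariate (limma; 611, 486 and 1799 genes at an unadjusted p under 0.05). With the striatal covariate the log2 differences were 0.67 for Syt6, 0.53 for Rasgrf1, -0.93 for Tenm1 and -0.66 for Kcnab1, so the loss of these calls does not show that striatal signal accounts for them. The gene count ran from 1 to 6 with 1 array left out and was 3 or 4 under the other 8 alternatives, of which a repeated quantile normalization and median centring moved the 4 differences by at most 0.000724 and say nothing about stability. Syt6 passed in 16 of 19 alternatives, Rasgrf1 and Tenm1 in 8 of 19 and Kcnab1 in 6 of 18, with signs kept throughout. Nr2f1 and Neurod6 passed in 0 of 19, with differences from -0.44 to -0.19 and from -0.24 to -0.09. The count of 8 lists became 4 with array weights and 0 with estimated correlation or fry, and ran from 4 to 11 with 1 array left out (4 without WT 38, 5 without WT 27). Cell division and radial glia lists passed in all 19 camera alternatives with the preset correlation and the striatal list in 18, the exception being the covariate made from 5 of its own members, whose effect on that call is built in. The glutamate receptor list's median ran from -0.0818 to 0.0323 with 1 array left out, turning without WT 38. The interneuron list turned to lower with the striatal covariate (median -0.0146, adjusted p 0.00172, from a main value of 0.477). The share of the first component was 31.2% with all probe sets. Of 679 values of named genes with 1 array left out, 657 kept their side of the threshold, as did 1133 of 1151 under other alternatives. For lists these were 188 of 210 and 334 of 360. These include 2, 6, 13 and 16 values that changed sign while past the threshold neither before nor after. The counts for genes do not measure stability, since most named genes lay far from the threshold throughout. Of the 4 genes called, Syt6 stayed past it in 7 of 7 fits with 1 array left out. Rasgrf1 and Tenm1 did so in 1 of 7 and Kcnab1 in 0 of 7. Where no reason is given, the cause was not tested. Probe sets dimmer than 6.84 entered 2 alternatives alone, no filter and all probe sets.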

Other observations

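The genes of this part were chosen after their values were seen, and none passed limma's adjustment over all genes. At an unadjusted p under 0.05, 21 genes were lower and 12 higher in CKO by more than 0.5 on the log2 scale, while at that p without a cut on size 422 were lower and 674 higher; the balance was not tested. Tafa1, which encodes a secreted chemokine-like protein of the brain, differed by -1.42 (SE 0.285, adjusted p 0.418), or 0.373 of the WT signal. The 4 CKO arrays were at 7.94 to 9.28 and the 3 WT arrays at 9.74 to 9.85. Its relative Tafa2 differed by -0.76 (SE 0.137, adjusted p 0.325). Sphkap, a protein that anchors protein kinase A, differed by -0.85 (SE 0.131), the glycosyltransferase gene Galnt14 by -0.73 (SE 0.126) and Mctp1, a protein with C2 domains, by -0.68 (SE 0.126). Among membrane proteins of neurons, the acid-sensing channel gene Asic2 differed by -0.54 (SE 0.094), the nicotinic receptor gene Chrna7 by -0.30 (SE 0.042, adjusted p 0.134), the synaptic adhesion gene Lrrtm3 by -0.32 (SE 0.061) and the synaptotagmin gene Syt4 by -0.43 (SE 0.083). For each of these 9 genes all 4 CKO arrays lay below all 3 WT arrays.

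The neuropeptide gene Cck differed by -0.38 (SE 0.109) and the netrin receptor gene Unc5c by -0.30 (SE 0.088). Fgfr4, a fibroblast growth factor receptor gene, differed by 0.29 (SE 0.049, adjusted p 0.301) without overlap, while Fgf8 differed by 0.10 (SE 0.092). Of the 20 interneuron markers, a list that did not shift, Dlx2 differed by 0.51 (SE 0.178), Dlx5 by 0.39 (SE 0.116) and Sp9 by 0.35 (SE 0.126), with overlapping groups. On CKO 4 these 3 were at 10.97, 10.01 and 9.99, inside the WT range, as Isl1 was at 7.74, and with the striatal covariate their differences lay between -0.04 and 0.05. AA388235 was at 8.68 to 8.92 on 3 CKO arrays, while CKO 1 and the 3 WT arrays lay below 6.84, the cut for dim probe sets, where a signal over background is not shown and the size of a difference cannot be read.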
